A study of Mus musculus with 2 samples.

How the data were processed

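The series compared 2 single-cell RNA libraries from the CNS of mice of 6 to 8 weeks, 1 of healthy mice and 1 of mice engrafted with LMO2 leukemia. Per the labels' protocols, mice were perfused through the heart, immune cells were enriched on a Percoll gradient, myeloid cells and T-ALL cells were sorted, and libraries were made with a 10x Genomics 3' kit and sequenced on an Illumina NovaSeq. The deposited files hold raw UMI counts per gene and barcode, which the authors made with Cell Ranger on the mm10 mouse genome and handled with Seurat 4.1.1, per the submitters' processing notes. The version of Cell Ranger, the gene annotation, and the number of mice behind each library are not given in the sources used here. Groups were taken from the titles in the labels.

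The counts were read in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, clustered with leidenalg 0.10.2 and igraph 0.11.9, and drawn with matplotlib 3.10.9. Each matrix had 32285 genes. Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept, which left 4647 of 5628 healthy and 4687 of 4769 leukemic barcodes, as 953 healthy and 71 leukemic barcodes exceeded the mitochondrial limit. Doublets were scored by similarity to simulated pairs (2 simulated per cell) and the highest scores were removed at a rate of 0.8% per 1000 barcodes (209 healthy and 179 leukemic barcodes). Barcodes with markers of more than 1 cell family were also removed (330 and 287), so that 417 healthy and 383 leukemic barcodes left in all. A barcode counted as mixed when at least 3 UMIs and at least 0.15 (microglia 0.2) of the median marker share in the 60 highest cells were found for the exclusive markers of at least 2 families.

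Cells of both libraries were log-normalised, and 2000 variable genes, 30 principal components, 20 neighbours and a Leiden resolution of 1.0 gave the first clusters. Myeloid and lymphoid clusters were clustered again with 20 components and a resolution of 1.5, for 43 clusters in all. Clusters were named from marker sets of 20 classes by the highest mean log2 level over the median cluster, with a score of at least 1.0 and at least 3 markers at 20 CPM, and 14 classes were named, with both conventional dendritic sets merged. The markers, gene lists, rule for named genes, filters and most alternatives were fixed before the data were examined. The naming thresholds, the second clustering, the rule for mixed barcodes, and the rule that left clusters mixed with microglia, or led by at least 3 of 4 granulocyte progenitor genes, without a name were set after the data were seen. An earlier form of the rule for mixed barcodes had removed most neutrophil-like and B cell-like cells and was replaced. Unnamed cells made up 3.17% of the healthy and 3.69% of the leukemic cells.

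With 1 library per group, counts were summed over the cells of each class with at least 50 cells in each library (4 classes), and both values were given with exact Poisson intervals, shares with exact Clopper-Pearson intervals, and ratios with exact conditional binomial intervals, all at 95%. These cover counting error only. Neither animals nor library preparation were replicated, so preparation and condition cannot be told apart. A gene with 0 UMIs on one side was given a ratio against a floor of 3 UMIs over the class, and its exact interval reaches somewhat lower. Log2 ratios used a pseudocount of 10 CPM. List medians used members with at least 20 UMIs in the class over both libraries, with intervals from 2000 Poisson redraws and a percentile among 10000 random lists matched on expression in 50 bins; genes with 0 UMIs placed at the floor gave the same medians. The 17 gene lists were interferon response, MHC class II, MHC class I, disease-associated microglia, homeostatic microglia, chemokines and cytokines, cell cycle, T-cell growth and niche ligands, adhesion and integrins, efferocytosis and complement, glycolysis and hypoxia, immune checkpoint and suppression, dissociation stress, Notch in T-ALL, LMO2 programme, T-ALL surface and growth receptors, and sex genes.

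Named genes were, per class, the 10 highest and 10 lowest ratios in microglia-like cells and the 6 highest and 6 lowest in other classes, among genes with at least 50 CPM and 30 UMIs on the higher side. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, T-cell receptor, sex and unnamed predicted genes were left out, as were genes under 20% of their highest CPM over the classes of that library. The order was by log2 ratio. The rule also took, per list, the 2 members furthest in the direction of the median and the 1 furthest the other way, Igf1 in myeloid classes, Igf1r in T-lineage-like cells, and all measured members of the T-ALL lists. A gene that the rule took is not reported here. Gene positions came from the GENCODE vM21 annotation of GRCm38/mm10, matched by Ensembl identifier; the annotation behind the counts was not used here.

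Free RNA was gauged from T-lineage markers in microglia-like cells, at 5.93 CPM in the healthy and 19.2 CPM in the leukemic library, which corresponds to 1.87% and 0.409% of the library profile. Sex genes were given no list median. Shares of cells with a UMI and genes per cell were also taken after thinning each cell to 2000 UMIs; in microglia-like cells 37 healthy and 16 leukemic cells were shallower and left out, in T-lineage-like cells 5 and 2, in non-classical monocyte-like cells 0 and 9, and in classical monocyte-like cells 2 and 0. Median genes per cell in microglia-like cells were 2977 and 2420, and 1200.0 and 1178 after thinning.

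The interval method was tested on simulated counts with 200 genes changed 2-fold either way. Counts were drawn with Poisson noise from 1 pooled profile per class, without variation between cells or libraries. The rates that follow thus hold for counting error only, as the intervals assume. The interval excluded 1 for 90.0% of changed genes in the microglia simulation (13912 genes), 71.5% in classical monocytes (7706 genes), 70.0% in non-classical monocytes (7643 genes) and 73.0% in T-lineage cells (12913 genes), and held the true ratio for 95.7%, 96.1%, 96.3% and 96.4% of genes. A simulated list of 12 doubled genes reached percentile 100 in each.

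Alternatives covered a looser cell filter (200 genes, 20% mitochondrial UMIs), a stricter one (1000 genes, 5%), no doublet removal, classes from marker scores of single cells, CPM centred on the median gene with at least 100 UMIs, CPM without mitochondrial and ribosomal protein genes, each cell counted once, free RNA subtracted, list minimums of 5 and 100 UMIs, and a pseudocount of 1 CPM. Added after the data were seen were removal of doublets by score only, with mixed barcodes kept, and a comparison within clusters that hold at least 20 cells of each library, weighted equally.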

Results

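Single-cell RNA sequencing was used to compare immune cells of the central nervous system (CNS) of healthy mice with those of mice engrafted with LMO2 leukemia, a T-cell acute lymphoblastic leukemia (T-ALL). LMO2 is a transcriptional cofactor whose overexpression drives one form of T-ALL. After perfusion, cells had been sorted for the myeloid surface proteins CD11b and/or CD11c and for a T-ALL surface profile that includes the T-cell protein CD5. Each group consisted of 1 library, so no difference between the groups had a replicate check, no test between groups was made and no p-value is given. The healthy library held 5628 barcodes with 67479163 unique molecular identifiers (UMIs), and the leukemic library held 4769 barcodes with 66612736 UMIs. After the filter on cells and the removal of doublets, 4230 healthy and 4304 leukemic cells remained, with medians of 8939.5 and 9565.5 UMIs per cell. Values are UMIs of a gene per 1000000 UMIs of a cell class (CPM), and ratios are leukemic over healthy unless stated otherwise. All intervals are 95% intervals that cover counting error only, and those of CPM, shares and single-gene ratios are exact.

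The first comparison asked which cell types the CNS of healthy and leukemic mice held. T-lineage-like cells made up 38.7% (interval 37.2 to 40.2) of leukemic cells and 8.04% (7.24 to 8.90) of healthy cells. Microglia-like cells, the resident macrophages of the brain parenchyma, held similar shares of the myeloid cells, at 75.7% (74.0 to 77.4) in the healthy and 77.7% (76.0 to 79.3) in the leukemic library. Non-classical monocyte-like cells, the patrolling monocytes of blood, were 2.74% (2.14 to 3.45) of healthy and 13.1% (11.8 to 14.5) of leukemic myeloid cells. Conversely, neutrophil-like cells were 11.8% (10.6 to 13.1) of healthy and 1.19% (0.8003 to 1.71) of leukemic myeloid cells, or 15.1% and 2.53% with doublets left in. Classical monocyte-like cells were 4.48% (3.71 to 5.36) and 2.43% (1.85 to 3.12), or 6.40% and 4.65% by single-cell marker scores.

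Among the smaller myeloid classes, conventional dendritic-like cells made up 0.952% (0.611 to 1.41) of healthy and 2.51% (1.92 to 3.21) of leukemic myeloid cells (0.568% and 1.16% by single-cell marker scores), and plasmacytoid dendritic-like cells 2.14% (1.61 to 2.79) and 1.23% (0.834 to 1.76). Border macrophage-like cells, the macrophages of the meninges and perivascular spaces, took 1.43% (1.002 to 1.97) and 1.77% (1.28 to 2.38), an order that single-cell marker scores turned, at 1.02% and 0.813%. Mast or basophil-like cells numbered 20 and 2, and no cluster took this name under either other cell filter or either other doublet rule. Several classes outside the myeloid and T-lineage gates held larger shares of the healthy library. Choroid plexus epithelium-like cells, led by Ttr, the gene of the thyroxine carrier transthyretin, made up 23.2% (22.0 to 24.5) of healthy and 0.534% (0.339 to 0.801) of leukemic cells. With the stricter cell filter these shares were 8.90% and 0.282%. NK or innate lymphoid-like cells made up 2.60% (2.14 to 3.13) and 0.604% (0.395 to 0.884). B cell-like (63 cells), astrocyte-like (45 cells) and erythroid-like cells (35 cells) were seen in the healthy library and in 0 of 4304 leukemic cells. A floor of 3 cells allows a leukemic share of up to 0.0697% for each, and the exact interval up to 0.0857%. With the looser cell filter erythroid-like cells made up 3.41% of healthy and 0.576% of leukemic cells. No cluster was named as migratory dendritic cells, endothelium, oligodendrocytes, neurons, or fibroblasts and mural cells. Each cluster took only its highest-scoring class, so such cells within other clusters are not ruled out. In all, 134 healthy (3.17%) and 159 leukemic cells (3.69%) stayed unnamed. All shares depend on the sort and on how the sorted fractions were combined, which the sources used here do not give. The healthy library held 23.2% of cells of a type that the stated sort should leave out, so whether it was sorted as stated is open, and with it what the shares of all cells measure.

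**Figure D1:**
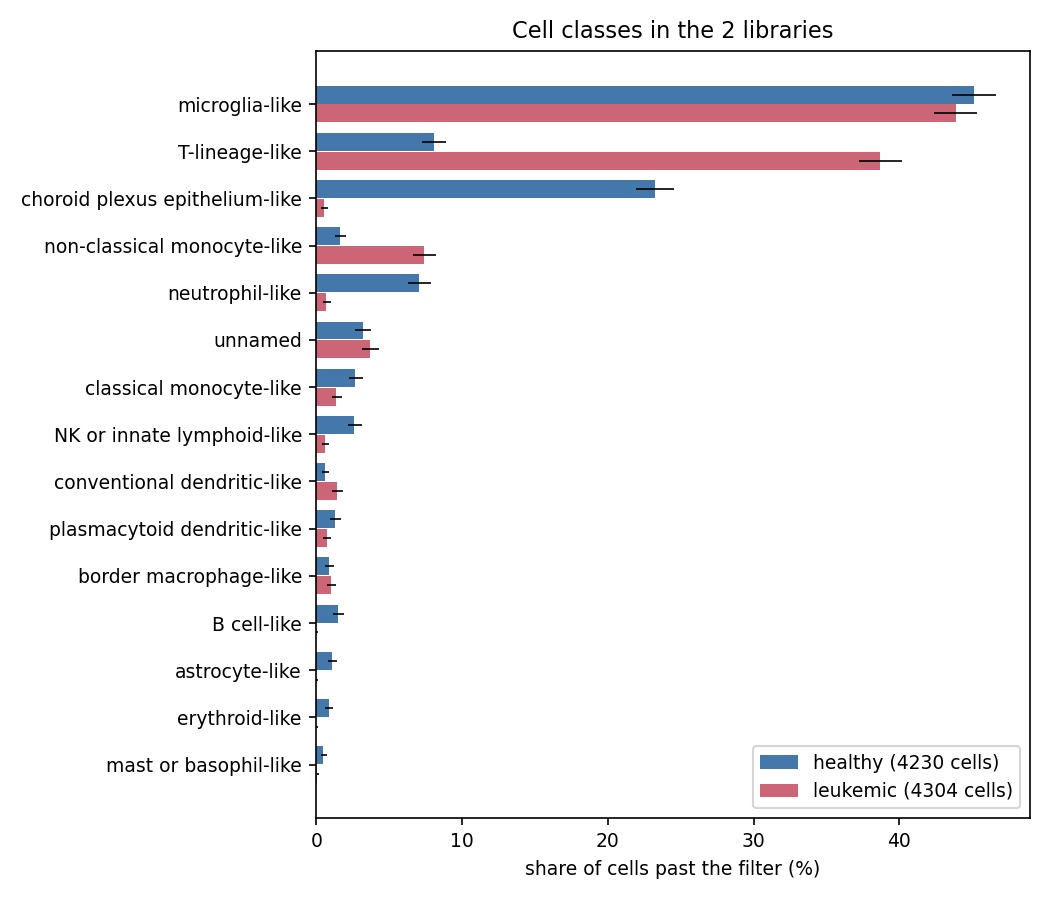
Share of cells (x axis, percent of cells past the filter) in each named class (y axis) of the healthy library (4230 cells) and the leukemic library (4304 cells); bars are shares and black lines exact 95% binomial intervals, which cover counting error only. T-lineage-like and non-classical monocyte-like cells took larger shares of the leukemic library, and choroid plexus epithelium-like and neutrophil-like cells of the healthy library.

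Next, gene levels were compared in microglia-like cells (1908 healthy cells with 22946646 UMIs, 1888 leukemic cells with 14232541 UMIs) to ask how these cells differed in the leukemic CNS. Differences were small for most genes. Ccl2, the chemokine that attracts monocytes (chromosome 11, 82035571 to 82037453, plus strand, GRCm38/mm10), stood at 200.2 CPM (194.5 to 206.1) in healthy and 312.0 CPM (302.9 to 321.3) in leukemic cells, 1.56-fold higher (1.495 to 1.62). The chemokine and cytokine list had a median log2 ratio of 0.25 (0.19 to 0.30), with 12 of 16 measured members higher in the leukemic library (10 with an interval above 1). The glycolysis and hypoxia list had a median of 0.25 (0.19 to 0.29), with 10 of 12 higher (8 with an interval above 1), among them Pgam1 at 1.45-fold (1.36 to 1.55) and Ldha at 1.36-fold (1.28 to 1.44). The interferon response list was lower, with a median of -0.17 (-0.20 to -0.09) and 16 of 18 members lower in the leukemic library, 10 of them with an interval below 1.

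Among antigen presentation genes, the MHC class I list had a median of 0.13 (0.07 to 0.17), led by the immunoproteasome subunits Psmb8 at 1.33-fold (1.27 to 1.40) and Psmb9 at 1.25-fold (1.16 to 1.34), with Erap1 the furthest the other way at 0.885-fold (0.803 to 0.974). The MHC class II list stood at -0.003 (-0.11 to 0.09), with H2-DMa at 1.23-fold (1.17 to 1.28) and H2-Aa at 0.513-fold (0.397 to 0.658), although 27% of the healthy H2-Aa UMIs came from 1 cell. Clusters left unnamed did not enter this median. A first held 64 healthy and 87 leukemic cells, with H2-Aa at 898.0 and 1438.5 CPM and the microglia marker P2ry12 at 2059.1 and 1679.5 CPM. A second held 7 and 21 cells, with H2-Aa at 6837.3 and 5276.6 CPM and P2ry12 at 602.4 and 607.7 CPM. Their median depths were 30996 and 24970 UMIs in the first and 22825 and 20151 UMIs in the second. Microglia-like cells had medians of 7759 and 5716 UMIs. Barcodes that held more than 1 cell are therefore not ruled out in these clusters. The list of genes induced in disease-associated microglia had a median of 0.13 (0.08 to 0.18), with 11 of 16 members higher, 9 of them with an interval above 1. Its leading members were Apoe, the gene of a lipid carrier, at 997.4 CPM (984.5 to 1010.4) in healthy and 1507.0 CPM (1486.9 to 1527.3) in leukemic cells, and the low gene Lgals3 at 5.14 (4.26 to 6.16) and 15.2 CPM (13.2 to 17.3), with 21.8% of its leukemic UMIs in 1 cell. The homeostatic microglia list was split evenly, with 8 members higher, 8 lower and a median of -0.011 (-0.027 to 0.007), with Siglech at 0.824-fold (0.807 to 0.842) and Cst3 at 1.20-fold (1.196 to 1.204). Cell cycle genes stood at a median of 0.12 (0.07 to 0.20), with Stmn1 at 1.76-fold (1.58 to 1.96). T-lineage markers were higher in these cells too, at 5.93 CPM in the healthy and 19.2 CPM in the leukemic library. A UMI of the T-cell receptor gene Trbc2 was seen in 0.472% (0.216 to 0.894) and 4.34% (3.47 to 5.36) of microglia-like cells, and the cell cycle list was also higher in leukemic T-lineage-like cells, at a median of 2.02 (1.90 to 2.22). With free RNA subtracted the cell cycle median in microglia-like cells was 0.162. That setting took 1.87% of the library profile from the healthy but 0.409% from the leukemic cells. It therefore does not settle whether RNA of T-lineage cells adds to the difference.

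Medians of the remaining lists lay near 0. They were -0.008 (-0.10 to 0.04) for T-cell growth and niche ligands, -0.028 (-0.07 to 0.011) for adhesion and integrins, -0.005 (-0.07 to 0.06) for efferocytosis and complement, -0.05 (-0.09 to 0.02) for immune checkpoint and suppression, and -0.08 (-0.09 to -0.07) for dissociation stress, which stood at percentile 14.2 of matched random lists. The highest ratios by the fixed rule were those of Dynll1 at 1.71-fold (1.62 to 1.80), Crybb1 at 1.68-fold (1.63 to 1.73), Slc39a1, Zfp691, Paip1, Ccl2, Cybc1, Bhlhe41, Rnaset2b and Hspa8, down to 1.41-fold (1.38 to 1.44). The lowest were those of Cmss1 at 0.172-fold (0.165 to 0.179), Cdk8 at 0.296-fold (0.284 to 0.309) and Lars2 at 0.390-fold (0.366 to 0.415), followed by Gphn, Purb, Nlrp1b, Hnrnpa0, Mlxip, Camk1d and Hspa1b at 0.555-fold to 0.618-fold. Cmss1, Cdk8 and Lars2 were lower in the leukemic library in the other compared classes as well.

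Among 10000 random lists matched on expression, the percentile of the median was 0.16 for interferon response, 99.1 for MHC class I, 99.5 for disease-associated microglia, 99.96 for glycolysis and hypoxia and 100 for chemokines and cytokines and for cell cycle. With the shared clusters weighted equally, an alternative chosen after the data were seen, the MHC class I median turned to -0.009 and the disease-associated microglia median fell to 0.002. In that setting Apoe turned from a log2 ratio of 0.59 to -0.10. The cluster with the most UMIs per cell held 695 healthy and 227 leukemic cells. The smallest cluster, with 42 and 62 cells, had the same weight. Which clusters moved the values was not tested. Classes drawn from single-cell marker scores also took in cells of the unnamed clusters. They gave an MHC class II median of 1.05 and an interferon median of -0.07. Since the unnamed clusters may hold barcodes of more than 1 cell, neither value need describe microglia-like cells alone. The pseudocount of 1 CPM gave an interferon median of -0.27. Counting each cell once gave a cell cycle median of 0.037 and the pseudocount of 1 CPM one of 0.39. The glycolysis median was 0.15 with the shared clusters weighted equally, and Ccl5, at 2.80-fold (2.39 to 3.30), took 39.7% of its leukemic UMIs from 1 cell.

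**Figure D2:**
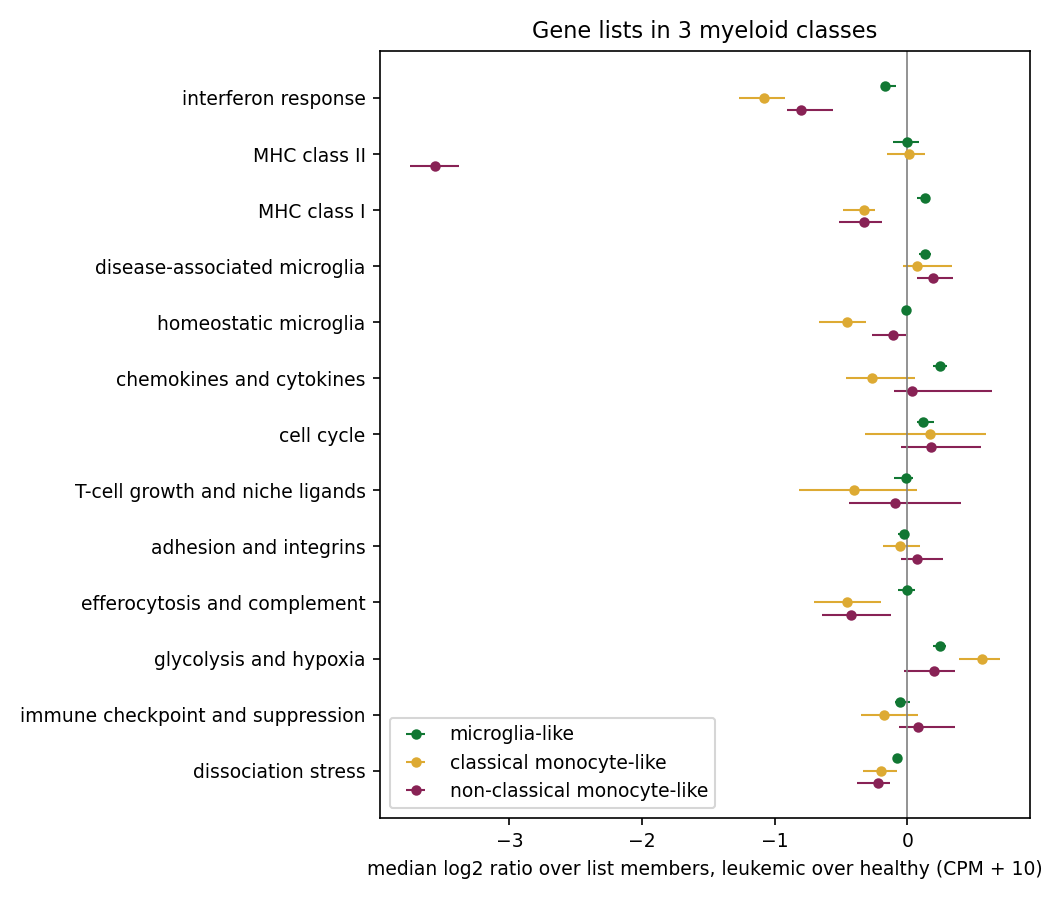
Median log2 ratio, leukemic over healthy (x axis, on CPM plus a pseudocount of 10), of the measured members of each gene list (y axis) in 3 myeloid classes; points are medians and lines 95% intervals from Poisson redraws of the counts. The interferon response medians were -0.17 in microglia-like, -1.09 in classical monocyte-like and -0.80 in non-classical monocyte-like cells.

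Classical monocyte-like cells (113 healthy and 59 leukemic cells, with 1435517 and 780910 UMIs, all from 1 cluster) were lower in interferon response genes in the leukemic library. The list had a median log2 ratio of -1.09 (-1.27 to -0.93), below all 10000 matched random lists, and 19 of 19 measured members were lower, 18 of them with an interval below 1. Rsad2, an antiviral enzyme, was 10.3-fold lower (3.88 to 38.9), at 52.9 CPM (41.7 to 66.3) in healthy and 5.12 CPM (1.40 to 13.1) in leukemic cells, with 27.6% of the healthy UMIs in 1 cell. Cxcl10, an interferon-induced chemokine (chromosome 5, 92346638 to 92348889, minus strand), had 115 healthy and 0 leukemic UMIs. That is 20.9-fold lower against a floor of 3 UMIs over the class, with an exact lower bound of 16.7-fold, but 60% of the healthy UMIs came from 1 cell. Oasl2 was 4.96-fold lower (2.999 to 8.73) and Ifi206, outside the list, 6.60-fold lower (3.22 to 15.7).

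Glycolysis and hypoxia genes went the other way in these cells. Their median was 0.56 (0.39 to 0.70), above all 10000 matched lists, with 9 of 11 members higher (7 with an interval above 1). Pgk1 stood at 2.04-fold (1.67 to 2.49) and Ldha at 1.86-fold (1.54 to 2.25), and Hk2 at 0.689-fold (0.546 to 0.866). The neutrophil-attracting chemokine Cxcl2 was 5.22-fold higher (3.66 to 7.57) and Ccl2 2.97-fold higher (2.24 to 3.97). Tppp3 was 5.055-fold higher (3.66 to 7.08), and Vcan, one of the markers that named the class, 3.21-fold higher (2.57 to 4.03). Abcc3 and Gpd2 were also among the 6 highest, but 90% and 79.4% of their leukemic UMIs came from 1 cell each, and Gpd2 turned to a log2 ratio of -0.10 with the looser cell filter. Cmss1 was 6.65-fold lower (5.78 to 7.68) and Cdk8 3.55-fold lower (2.96 to 4.27).

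The other lists in classical monocyte-like cells had medians of -0.33 (-0.49 to -0.24) for MHC class I, -0.46 (-0.67 to -0.31) for homeostatic microglia genes, -0.46 (-0.71 to -0.20) for efferocytosis and complement, -0.20 (-0.34 to -0.08) for dissociation stress and -0.26 (-0.47 to 0.06) for chemokines and cytokines. Complement C3 was 2.30-fold lower (1.84 to 2.91) and lipoprotein lipase, Lpl, 4.35-fold lower (2.66 to 7.55). C1qa was 4.86-fold lower (2.89 to 8.74), with 46.2% of its healthy UMIs in 1 cell, and C1qb 1.33-fold higher (1.01 to 1.73), with 46.5% of its leukemic UMIs in 1 cell. The stress median stood at percentile 15 and the efferocytosis median at percentile 2.9 of matched random lists. Medians of MHC class II at 0.009 (-0.15 to 0.13), disease-associated microglia at 0.07 (-0.04 to 0.33), cell cycle at 0.17 (-0.32 to 0.59), niche ligands at -0.41 (-0.81 to 0.07), adhesion at -0.06 (-0.18 to 0.10) and checkpoint genes at -0.18 (-0.35 to 0.08) had intervals that included 0. With single-cell marker scores the interferon median was -0.74, the glycolysis median 0.22 and the MHC class I median -0.17, while the efferocytosis and stress medians turned to 0.22 each and the MHC class II median was 1.78. The efferocytosis median was -0.03 with the looser and with the stricter cell filter. The MHC class II median also lay between -0.46 and 0.57 under the other cell filters, doublet rules and cell weights.

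Non-classical monocyte-like cells (69 healthy and 319 leukemic cells, with 513904 and 1600168 UMIs) were compared next. In the leukemic library these cells were higher in Il10, the gene of an anti-inflammatory cytokine (chromosome 1, 131019845 to 131024974, plus strand), with 0 healthy and 89 leukemic UMIs. That is 9.53-fold higher against a floor of 3 UMIs over the class, with an exact lower bound of 7.59-fold. An Il10 UMI was seen in 45 of 319 leukemic cells (14.1%, 10.5 to 18.4) and in 0 of 69 healthy cells. A floor of 3 cells allows a healthy share of cells with a UMI of up to 4.35%, and the exact interval up to 5.21%. The leukemic share was 7.74% after thinning to 2000 UMIs. In leukemic T-lineage-like cells, a measure of background from free RNA, the unthinned share was 0.180%. Median depths of these 2 leukemic classes were 4674 and 17312 UMIs. The chemokine Ccl4 was 24.1-fold higher (6.55 to 201), the inhibitory receptor Siglece 11.4-fold (4.81 to 35.6), the kinase Ikbke 10.5-fold (4.01 to 39.2), the lectin Clec4n 7.71-fold (3.46 to 21.4), the adhesion molecule Pecam1 6.46-fold (4.45 to 9.73), thioredoxin, Txn1, 5.005-fold (4.23 to 5.965), and the tetraspanin Cd9 2.71-fold (2.33 to 3.18).

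Interferon response genes were again lower in the leukemic library, with a median of -0.80 (-0.91 to -0.56) and 11 of 12 members lower, 9 of them with an interval below 1. Oasl2 was 3.11-fold lower (1.59 to 6.10), with 40% of its healthy UMIs in 1 cell, and Rtp4 2.40-fold lower (1.40 to 4.08). Apoe was 4.08-fold lower (3.83 to 4.35), Flt1 10.3-fold (5.87 to 18.8), Slfn5 9.12-fold (4.87 to 18.1), with 36.6% of healthy UMIs in 1 cell, Stxbp6 6.39-fold (3.61 to 11.7), Arhgef37 5.92-fold (3.74 to 9.54), Cmss1 4.46-fold (4.15 to 4.80) and Cdk8 3.61-fold (3.21 to 4.06). The MHC class I list had a median of -0.33 (-0.52 to -0.19), with 10 of 12 members lower (8 with an interval below 1). B2m was 1.13-fold higher (1.06 to 1.19).

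MHC class II genes had the lowest list median in this class. The median was -3.56 (-3.75 to -3.38), with 6 of 6 members lower. H2-Ab1 stood at 667.4 CPM (598.7 to 741.9) in healthy and 15.6 CPM (10.1 to 23.1) in leukemic cells, and H2-Aa at 685.0 CPM (615.3 to 760.4) and 20.6 CPM (14.2 to 29.0). Cd74, the gene of the invariant chain that guides MHC class II molecules, stood at 2763.2 CPM (2621.3 to 2910.7) and 328.7 CPM (301.2 to 358.0), with a UMI in 53 of 69 healthy cells (76.8%, 65.1 to 86.1) and 101 of 319 leukemic cells (31.7%, 26.6 to 37.1), or 55.1% and 21.0% after thinning. An H2-Aa UMI was present in 9 of 69 healthy cells (13.04%, 6.14 to 23.3) and 10 of 319 leukemic cells (3.13%, 1.51 to 5.69), or 10.1% and 1.61% after thinning, and 1 healthy cell held 25.9% of the healthy H2-Aa UMIs. Most healthy UMIs of these genes lay in few cells. Leaving out the 10% of cells with the highest list share in each library (7 healthy and 32 leukemic cells) left 4 of 352 healthy H2-Aa UMIs, 4 of 343 of H2-Ab1 and 290 of 1420 of Cd74. The log2 ratios were then -0.53 for H2-Aa, -0.39 for H2-Ab1, -0.46 for H2-Eb1, -2.97 (-3.28 to -2.69) for Cd74, 0.36 for H2-DMa and 0.007 for H2-DMb1, with a list median of -0.425 (-0.763 to 0.055). Single-cell marker scores gave a list median of -0.93. H2-Aa was seen in 1.43% and Cd74 in 3.16% of healthy choroid plexus epithelium-like cells, which should lack them.

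The remaining lists in non-classical monocyte-like cells had medians of 0.19 (0.07 to 0.34) for disease-associated microglia genes, -0.11 (-0.27 to -0.010) for homeostatic microglia genes and -0.43 (-0.64 to -0.13) for efferocytosis and complement, with 7 of 7 members lower but 2 of them with an interval below 1. That of dissociation stress was -0.22 (-0.38 to -0.135). Among matched random lists the disease-associated and homeostatic medians stood at percentiles 86.3 and 10.7, so neither was unusual for genes of their level. Those of chemokines and cytokines (0.031, -0.10 to 0.64), cell cycle (0.18, -0.05 to 0.55), niche ligands (-0.10, -0.44 to 0.40), adhesion (0.07, -0.05 to 0.27), glycolysis (0.20, -0.03 to 0.36) and checkpoint genes (0.08, -0.065 to 0.355) had intervals that included 0. The libraries filled different clusters of this class, since 53 of the 69 healthy cells but 52 of the 319 leukemic cells lay in 1 cluster and 168 and 99 leukemic cells lay in clusters with 5 and 11 healthy cells. Within the cluster that both libraries filled, the interferon median was -0.40 (-0.46 over the class with members of at least 100 UMIs), Il10 had a log2 ratio of 1.85 against 2.71 over the class, and the stress and homeostatic medians turned to 0.14 and 0.004, while single-cell marker scores turned the efferocytosis median to 0.53 and the homeostatic median to 0.40.

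T-lineage-like cells of the leukemic library were then set against those of the healthy library (1665 and 340 cells, with 31495021 and 2507815 UMIs). These were largely different cells, because 1622 leukemic cells lay in 12 clusters with 6 healthy cells in all, and 334 healthy cells lay in 3 clusters with 43 leukemic cells. The leukemic cells were higher in Dntt, which adds bases at rearranging receptor genes of immature lymphocytes, at 36.4-fold (28.3 to 47.6). Arpp21 was 712-fold higher (243.5 to 3451.7, with 3 healthy UMIs) and Galk1 28.7-fold higher (22.3 to 37.4). Cpa3 was 719-fold and Lmcd1 294-fold higher against a floor of 3 UMIs (0 healthy UMIs each). Lower in the leukemic library were Klf2, a transcription factor of resting T cells, at 77.5-fold (68.1 to 88.5), Ms4a4b at 102-fold (91.9 to 114), Ifi27l2a at 78.6-fold (70.0 to 88.5), Cd52 at 46.4-fold (44.1 to 48.8) and Inpp4b at 254-fold (211 to 307). Jchain was the lowest by the rule (3786 healthy UMIs, 1 leukemic UMI), but 2 healthy cells held 97.9% of its UMIs. They were the only healthy cells of a cluster with 176 leukemic cells, whose leading genes included the immunoglobulin genes Igkc and Igha. These 2 cells may not be T-lineage cells, so the ratio shows no difference of Jchain in that lineage.

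The T-ALL lists differed in direction. For Notch genes in T-ALL the median was 1.255 (1.02 to 1.54), with 8 of 9 members higher. Hes1, a direct Notch target (chromosome 16, 30064384 to 30067796, plus strand), stood at 1.59 CPM (0.435 to 4.08) in healthy and 376.1 CPM (369.4 to 383.0) in leukemic cells, 236-fold higher (92.1 to 866). Ptcra, the pre-T-cell receptor chain, was 100-fold higher (27.8 to 829, with 2 healthy UMIs), Notch1 5.11-fold (4.01 to 6.62), Notch3 23.2-fold (7.92 to 113), Il2ra 3.13-fold (2.34 to 4.27), Myc 2.505-fold (1.87 to 3.44) and Dtx1 1.56-fold (1.18 to 2.09). Heyl was 3-fold higher against a floor of 3 UMIs, whereas Nrarp was at 0.487-fold (0.239 to 1.12).

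In the LMO2 programme, 6 of 8 members were higher (5 with an interval above 1) and the median was 0.74 (0.58 to 0.86). Its transcription factors Lyl1 and Hhex were 33.9-fold (16.4 to 84.4) and 20.5-fold (9.93 to 51.1) higher, Nfe2 9.06-fold (3.51 to 33.4), Mycn 6.29-fold (1.71 to 52.4, with 2 healthy UMIs), Kit 3.34-fold (2.12 to 5.57) and Gfi1b 1.99-fold (0.893 to 5.51). Mef2c was 47.95-fold lower (29.7 to 80.55), with 34.5% of its healthy UMIs in 1 cell. Lmo2 itself (chromosome 2, 103957986 to 103981878, plus strand) stood at 28.3 CPM (22.1 to 35.7) in healthy and 1.18 CPM (0.827 to 1.62) in leukemic cells, with 47.9% of the healthy UMIs in 1 cell. Its log2 ratio of -1.78 was -0.48 with each cell counted once and -0.02 with single-cell marker scores. The labels do not describe the LMO2 construct, and counts at the mouse gene do not measure a construct that lacks its 3' end, so this value checks no label.

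Of 17 surface and growth receptors, 15 were lower in the leukemic library, with a median of -2.58 (-2.63 to -2.38). They included Il7r at 67.8-fold (58.7 to 78.5), Ccr7 at 231-fold (149 to 378), Cxcr3 at 47.1-fold (36.3 to 61.9), Cd4 at 29.96-fold (22.5 to 40.2), Cd44 at 24.8-fold (19.0 to 32.6), Cd8a at 5.92-fold (5.35 to 6.56), Itgb2 at 11.6-fold (9.82 to 13.8), Itgb7 at 42.6-fold (35.2 to 51.9), Itgal at 2.33-fold (2.03 to 2.67), Itgb1 at 2.05-fold (1.90 to 2.22) and Itga4 at 1.85-fold (1.718 to 1.996). Cd5, Cd8b1 and Cd28, which are also markers that named the class, were 2.685-fold (2.33 to 3.08), 21.9-fold (20.1 to 24.0) and 7.75-fold (6.95 to 8.63) lower. Kit and Cxcr4 were higher, Cxcr4 at 1.46-fold (1.09 to 2.01).

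**Figure D3:**
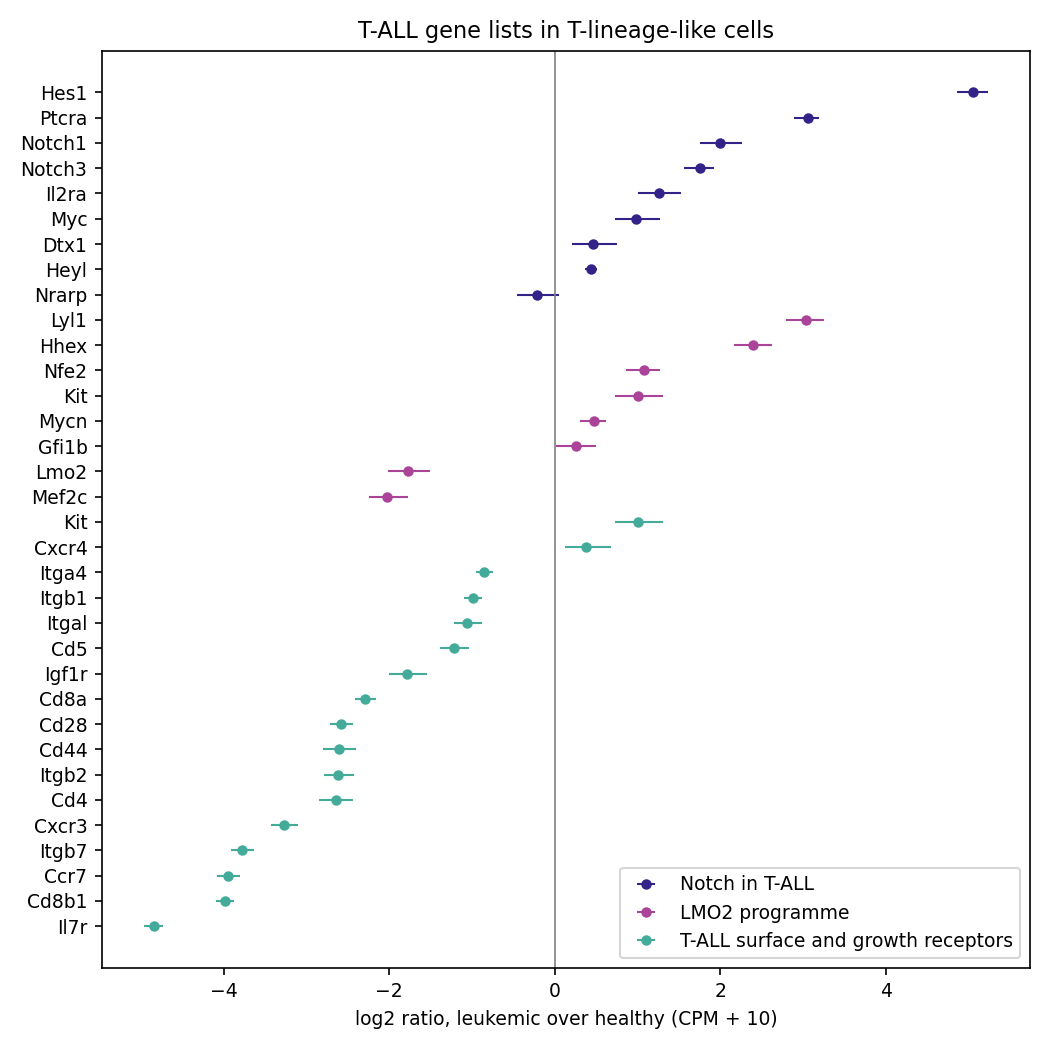
Log2 ratio, leukemic over healthy (x axis, on CPM plus a pseudocount of 10), of each measured member of 3 T-ALL gene lists (y axis, gene symbols) in T-lineage-like cells; points are ratios and lines 95% intervals from Poisson redraws of the counts. Kit belongs to 2 of the lists and is drawn in both. Most Notch members lay above 0 and 15 of 17 surface and growth receptors below 0.

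Cell cycle genes were higher in leukemic T-lineage-like cells throughout the list, with a median of 2.02 (1.90 to 2.22) and 15 of 15 members higher, Tyms at 10.45-fold (8.23 to 13.5) and Rrm2 at 10.1-fold (7.65 to 13.7). Glycolysis and hypoxia genes had a median of 0.94 (0.78 to 1.21), with 8 of 11 members higher, 7 of them with an interval above 1. Lower were MHC class I genes, with a median of -1.49 (-1.58 to -1.41) and H2-Q7 70.8-fold lower (62.0 to 80.9), while Tap2 was 3.07-fold higher (2.69 to 3.52). Interferon response genes had a median of -0.82 (-0.97 to -0.64), and dissociation stress genes one of -1.53 (-1.67 to -1.39) with 12 of 12 members lower (11 with an interval below 1). Medians were also lower for adhesion genes at -1.02 (-1.11 to -0.93), chemokines and cytokines -2.13 (-2.28 to -1.95), checkpoint genes -0.68 (-0.82 to -0.44), MHC class II genes -0.37 (-0.56 to -0.18) and efferocytosis and complement genes -0.41 (-0.65 to -0.17), with 49.5% of the healthy C1qa UMIs in 1 cell. Genes of disease-associated microglia, at -0.95 (-1.10 to -0.77), and of homeostatic microglia, at -1.05 (-1.20 to -0.87), were lower too, with 23.7% of the healthy Lgals3 UMIs and 15.9% of the healthy Cx3cr1 UMIs in 1 cell. Among matched random lists the MHC class II, efferocytosis and glycolysis medians stood at percentiles 8.21, 3.56 and 96.8. The MHC class II median was -1.004 with the pseudocount of 1 CPM and -0.06 with single-cell marker scores.

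Relative to the median gene of T-lineage-like cells, whose log2 ratio was 0.15, the cell cycle median was 1.88. Within the only cluster that both libraries filled (164 healthy and 43 leukemic cells), the cell cycle, Notch and LMO2 medians turned to -0.14, -0.32 and -0.10. MHC class I, disease-associated and checkpoint medians turned to 0.08, 0.07 and 0.005. Some members rest on few UMIs there, where the pseudocount holds ratios near 0, so the Notch and LMO2 medians do not show lower levels. Every other T-lineage cluster held fewer than 20 cells of 1 of the libraries. The pseudocount of 1 CPM gave a Notch median of 2.20 and an LMO2 median of 1.68, and leaving doublets in gave an LMO2 median of 0.49.

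Igf1 and Igf1r were followed in every class, since IGF1 is a growth factor made by macrophages and IGF1R its receptor. Igf1 (chromosome 10, 87858265 to 87937042, plus strand) was highest among the myeloid classes in border macrophage-like cells, at 86.5 CPM (54.2 to 131, 22 UMIs) in 36 healthy cells and 45.8 CPM (25.6 to 75.5, 15 UMIs) in 43 leukemic cells, with overlapping intervals. In microglia-like cells it stood at 3.88 CPM (3.11 to 4.77) and 2.67 CPM (1.89 to 3.66), and an Igf1 UMI was seen in 1.94% (1.37 to 2.66) and 1.17% (0.732 to 1.76) of cells, or 0.267% of cells in each library after thinning. The same shares were 0.294% and 0.180% in T-lineage-like cells, at median depths of 6514.5 and 17312 UMIs against 7759 and 5716 UMIs in microglia-like cells. In choroid plexus epithelium-like cells they were 2.65% (1.74 to 3.855) of healthy cells and 3 of 23 leukemic cells (13.04%, 2.775 to 33.6). The leukemic T-lineage-like share gives no background level for leukemic microglia-like cells, since Ttr, which neither should express, stood at 2.73 CPM (2.18 to 3.37) in the former and 227.3 CPM (219.5 to 235.3) in the latter. Classical and non-classical monocyte-like cells and both dendritic classes had between 0 and 2 Igf1 UMIs in each library, and neutrophil-like cells had 6 and 1, so a difference was not detectable there at this depth.

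Igf1r (chromosome 7, 67952827 to 68233668, plus strand) was 8.29-fold lower (6.42 to 10.7) in leukemic T-lineage-like cells, at 41.9 CPM (34.2 to 50.7) in healthy and 5.05 CPM (4.29 to 5.90) in leukemic cells. An Igf1r UMI was present in 51 of 340 healthy cells (11.4% to 19.25%) and 137 of 1665 leukemic cells (8.23%, 6.95 to 9.65), and in 4.78% and 0.962% after thinning. Within the shared T-lineage cluster the log2 ratio was -0.30 against -1.785 over the class. Microglia-like cells had 111.8 CPM (107.5 to 116.2) and 97.4 CPM (92.3 to 102.6).

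Border macrophage-like, dendritic and neutrophil-like cells had fewer than 50 cells in at least 1 library, so no named genes or list medians were compared in them. A simulated 2-fold change was detected, as an interval that excluded 1, for 71.5% and 70.0% of changed genes in classical and non-classical monocyte-like cells, 73.0% in T-lineage-like and 90.0% in microglia-like cells. The simulation held counting error only, with no variation between cells, so these rates need not carry over to the measured cells.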

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

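Both results of this part were chosen for a closer look after the data had been seen, and neither belongs to a comparison of the report. The first is a signal in barcodes that failed the filter on cells. Of the UMIs in 981 such healthy barcodes, 18.8% (exact interval 18.7 to 18.8) belonged to Ttr, the leading gene of choroid plexus epithelium, against 2.22% (2.14 to 2.30) in 82 leukemic barcodes. The sort took CD11b, CD11c or CD5 positive cells, none of which should be choroid plexus epithelium.

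The second is a cluster that was left without a name because granulocyte progenitor genes led it. It held 63 healthy and 51 leukemic cells. Mpo stood at 2608.6 CPM in its healthy and 95.3 CPM in its leukemic cells, Prtn3 at 4040.1 and 959.8 CPM, Elane at 3816.3 and 388.7 CPM, and Ctsg at 2077.5 and 360.4 CPM. H2-Aa, a gene of antigen-presenting cells, went the other way, at 147.1 and 763.2 CPM, so a different make-up of the cluster in the 2 libraries is not ruled out. The difference was not tested, since each group has 1 library.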

How the results depend on the processing

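Removal of doublets by score only, with mixed barcodes kept, and the comparison within clusters filled by both libraries were chosen after the data were seen, as were the list results treated as main, which were picked from the list medians before any alternative was run. No paired analysis was possible because each group holds 1 library. Of the values under alternatives, 537 list medians stayed the same, 148 moved and 13 reversed. Of the named-gene values, 1923 stayed, 549 moved and 47 reversed. Of the shares, 116 stayed and 24 moved. Reversal was counted only for medians and genes whose main interval left out 0, so shares and the other medians could not count as reversed. Of 24 depth values, 22 were counted as moved under thinning. Genes per cell always were, and thinned shares were set against intervals of unthinned cells. With at least 100 UMIs, 50 of 54 list medians could be computed. Where a setting changed a value, the cause was not tested unless stated. Values below are log2 ratios, with the main value first.

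Looser cell filter: in classical monocyte-like cells the MHC class II median went from 0.009 to 0.544, Gpd2 from 1.939 to -0.096 and H2-Eb1 from -0.542 to 0.159, and in non-classical monocyte-like cells the MHC class II median from -3.56 to -3.076. Stricter cell filter: the healthy T-lineage-like share went from 8.038% to 9.539%, the classical MHC class II median to 0.448 and H2-Eb1 to 0.179. No doublet removal: the healthy microglia-like share of myeloid cells went from 75.68% to 73.09%, the leukemic T-lineage-like share from 38.68% to 37.08%, the classical MHC class II median to 0.321, classical H2-Eb1 to 0.045, the non-classical MHC class II median to -2.714, the LMO2 median from 0.74 to 0.488, and Tgfbr1 in T-lineage-like cells from 0.34 to -0.896. Mixed barcodes kept: the leukemic T-lineage-like share was 37.11%, the classical MHC class II median 0.569, classical H2-Eb1 0.285, and the T-lineage cell cycle median went from 2.021 to 2.312.

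Single-cell marker scores: in microglia-like cells the interferon median went from -0.166 to -0.074, MHC class II from -0.003 to 1.054, MHC class I from 0.132 to 0.174, homeostatic from -0.011 to -0.078, H2-Aa from -0.438 to 1.453 and H2-Eb1 from -0.372 to 1.423. In classical monocyte-like cells the interferon median went from -1.085 to -0.74, MHC class II to 1.779, efferocytosis from -0.455 to 0.224, stress from -0.203 to 0.216, H2-Eb1 to 2.32, Lpl from -1.739 to 0.382, Mki67 from -0.988 to 0.141, C1qa from -1.846 to 1.286 and Jun from -0.734 to 0.315. In non-classical monocyte-like cells the MHC class II median went to -0.934, homeostatic from -0.11 to 0.399, efferocytosis from -0.429 to 0.531 and P2ry12 from -0.88 to 0.951. In T-lineage-like cells the cell cycle median went to 2.357 and Jchain from -7.243 to 0.005.

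CPM centred on the median gene: in microglia-like cells MHC class I went to 0.195, disease-associated microglia from 0.131 to 0.193 and homeostatic to 0.052, and the T-lineage cell cycle median to 1.875. Each cell counted once: the classical MHC class II median went to -0.461, the non-classical one to -3.237, T-lineage cell cycle to 2.43 and LMO2 to 0.998. Free RNA subtracted: the microglia MHC class II median went to 0.128 and non-classical P2ry12 to 0.514. List minimum of 5 UMIs: non-classical MHC class II -3.033 and LMO2 0.476. List minimum of 100 UMIs: non-classical interferon from -0.8 to -0.463 and MHC class II -4.087. Pseudocount of 1 CPM: interferon -0.267 in microglia-like, -1.291 in classical and -0.925 in non-classical cells, disease-associated microglia 0.189, non-classical MHC class II -3.835, T-lineage cell cycle 2.355, Notch from 1.255 to 2.198 and LMO2 1.679.

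Clusters filled by both libraries, weighted equally: in microglia-like cells interferon went to -0.272, MHC class I to -0.009, disease-associated microglia to 0.002, Erap1 from -0.147 to 0.076, Apoe from 0.591 to -0.104 and Pcna from -0.107 to 0.039. In non-classical monocyte-like cells interferon went to -0.4, MHC class II to -2.744, homeostatic to 0.004 and stress from -0.222 to 0.136. In T-lineage-like cells only 1 cluster, with 164 healthy and 43 leukemic cells, enters this setting, so its values leave out 1622 of 1665 leukemic cells by construction. There MHC class I went from -1.489 to 0.08, disease-associated microglia from -0.948 to 0.071, cell cycle to -0.135, checkpoint from -0.68 to 0.005, Notch to -0.321 and LMO2 to -0.1. Genes higher over the class had ratios below 0 there: Arpp21 (6.266 to -0.235), Ptcra (3.059 to -0.235), Lyl1 (3.031 to -0.235), Rrm2 (2.815 to -0.186), Notch1 (1.993 to -0.321), Notch3 (1.755 to -0.34), Itga9 (1.36 to -0.235), Lrp1 (1.276 to -0.438), Il2ra (1.255 to -1.642), Cenpa (1.164 to -0.207), Kit (1.005 to -0.846), Myc (0.981 to -0.122), Tgfb1 (0.73 to -0.6), Mycn (0.476 to -0.122) and Dtx1 (0.462 to -0.532). Arpp21, Ptcra, Lyl1 and Itga9 shared the value -0.235, and Myc and Mycn -0.122. Such equal values can arise at a few UMIs, where the pseudocount of 10 CPM holds ratios near 0. With 43 leukemic cells they do not show a lower level. Genes lower over the class turned higher: Ms4a4b (-5.828 to 0.084), Cd52 (-5.322 to 0.038), Cxcr3 (-3.275 to 0.038), Junb (-3.267 to 0.304), Vsir (-3.032 to 0.005), H2-K1 (-2.945 to 0.254), Cd28 (-2.579 to 0.019), Cd74 (-2.15 to 0.382), Zbp1 (-1.928 to 0.158), Eno1 (-1.611 to 0.313), H2-DMa (-1.23 to 0.612), Cd274 (-1.111 to 0.273) and Itga4 (-0.853 to 0.608).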

Other observations

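The tests of scaling, of a few healthy cells with high MHC class II genes or high Cd74, of nuclear RNA in classes other than microglia-like cells, and the upper bound for border macrophages were chosen only after the result was seen, and Gm42418 was added to its group after its values were seen. Xist, which is expressed from the inactive X chromosome, stood at 869.2 CPM (857.2 to 881.4) in healthy and 840.2 CPM (825.2 to 855.4) in leukemic microglia-like cells, and at 413.5 CPM (388.7 to 439.5) and 704.4 CPM (695.2 to 713.7) in T-lineage-like cells. The Y-linked gene Ddx3y had between 0 and 3 UMIs in each class of each library. Ttr stood at 453.8 CPM (427.8 to 480.9) in healthy and 2.73 CPM (2.18 to 3.37) in leukemic T-lineage-like cells, and at 528.8 CPM (519.4 to 538.3) and 227.3 CPM (219.5 to 235.3) in microglia-like cells.

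The interferon list was lower in leukemic monocyte-like cells. A few healthy cells with very high interferon genes may be excluded as the source, since leaving out the highest 10% of cells gave a median of -1.076 (-1.344 to -0.954) in classical monocyte-like cells. A shift of all genes between the libraries (scaling) is excluded too, since the median gene of this class had a log2 ratio of -0.079. Centring on it could therefore change the list median little, and gave -1.006 (-1.194 to -0.818). The width of that interval was carried over from the uncentred median and not redrawn. Different sub-clusters holding the non-classical monocyte-like cells could account for part of the difference there, since the median within the shared cluster was -0.4 (-0.82 to -0.215), and this test cannot tell. No biological explanation was tested.

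The MHC class II list was lower in leukemic non-classical monocyte-like cells. A few healthy cells with very high Cd74 are excluded as the only source for that gene. Its log2 ratio stayed at -2.974 (-3.276 to -2.694) without the 10% of cells highest in the list in each library. Those cells held all but 290 of its 1420 healthy UMIs. The same step left out 32 leukemic cells and left 113 leukemic UMIs of Cd74. How much of the untrimmed difference the few healthy cells carried was therefore not measured. For the list as a whole a few healthy cells with very high MHC class II genes stay open, because the median of -0.425 (-0.763 to 0.055) comes from leaving out cells by the list itself, 7 healthy cells where 9 had an H2-Aa UMI, which left 4 of 352 healthy UMIs of that gene. Conventional dendritic cells counted in this class might contribute, and their markers implied 17.3% (0.0 to 56.7) of the share that MHC class II genes required, which cannot tell. Border macrophage markers implied 0.0% (0.0 to 13.8) of the share required. Barcodes with markers of both border macrophages and monocytes had been removed, which favours a low value, so this test alone cannot exclude border macrophages. Different filling of the sub-clusters is excluded as the only source, since the median was -2.744 (-3.002 to -2.451) within the 1 cluster that both libraries filled. A few cells high in these genes within that cluster are not ruled out by it.

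Cmss1, Cdk8, Lars2 and Gm42418 were lower in the leukemic library in each of 10 classes compared. Mast or basophil-like cells, with 2 leukemic cells, were left out, and there Gm42418 stood at 11527.2 CPM in healthy and 15134.2 CPM in leukemic cells. A difference between the 2 library preparations that acts on every cell fits, since the median of the 4 genes was below -0.5 in 6 of 6 classes not looked at before, and it ranged from -1.47 to -2.835 over 10 classes. More nuclear RNA per cell in the healthy library is excluded as the source in microglia-like cells, because the nuclear RNAs Malat1, at -0.067 (-0.072 to -0.062), and Neat1, at -0.304 (-0.37 to -0.23), had a median of -0.185 (-0.222 to -0.15) there, against -1.677 for the 4 genes. Of the other 9 classes, the whole intervals of both RNAs lay above -0.5 in 2, neutrophil-like and choroid plexus epithelium-like cells. The values there argue against it, but these classes were singled out by the same values and held 29 and 23 leukemic cells. The lowest of their values was 0.033, with bounds down to -0.216, and Malat1 stood at 1.396 (1.313 to 1.478) in choroid plexus epithelium-like cells, against -1.938 and -2.262 for the 4 genes. In the remaining classes it stays open. Both RNAs were lower in T-lineage-like cells, at -1.508 (-1.522 to -1.495) and -1.847 (-2.041 to -1.633), while in NK or innate lymphoid-like cells Malat1 stood at -0.02 (-0.074 to 0.03) and Neat1, with 6 leukemic UMIs, at -1.371 (-2.65 to -0.534), and in classical monocyte-like cells the values were -0.469 (-0.521 to -0.421) and -0.425 (-0.726 to -0.144). Library preparation and condition coincide here, so a response of every cell to leukemia could not be separated from preparation.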
